A study of Mus musculus with 2 samples.

How the data were processed

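Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on Nacc1 in N2A cells, a mouse neuroblastoma line. The series holds 1 Nacc1 ChIP library and 1 input library, which received no antibody. Per the labels' protocols, about 20000000 cells were fixed in 1% formaldehyde and chromatin was precipitated with 4 µg of an antibody against Nacc1. Grouping followed the antibody label. There was no replicate of either library, so no value carries a replicate error, and all intervals and p-values below describe this single list of peaks.

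The data analysed were the peak list of the ChIP library, in BED format, with a position, a name and a score per peak. Per the submitters' processing notes, CASAVA 1.8, Bowtie2, SAMtools and MACS 1.4 were used, with the mouse build mm9. Their parameters, the read filters and the number of mapped reads are not given in the sources used here. MACS compares a ChIP library with a control library, and whether the input served as that control is not stated either. The score deposited for each peak is, in the output format of MACS 1.4, −10 times the log10 of the peak's p-value, so a score of 50 stands for a caller p-value of 1e-05 and a score of 100 for 1e-10. The lowest score in the list was 50. Exactly 3100 was listed for 5 peaks, and whether this is a limit of the caller is not stated, so scores at the top of the list are given as deposited. Scores rise with sequencing depth and with the width of a region as well as with enrichment. They were used only within this list, to describe, rank, filter and compare peaks. Peaks had been called on 1 library, with no pooling recorded. Read depth and signal per base were not analysed here, so no precision could be attached to the height of a single peak. Intervals on numbers of peaks cover counting error only.

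Positions were converted to 1-based coordinates and kept in mm9. The gene table at hand was built on GRCm38, another build, and coordinates were not converted. Consequently 5 planned results that need an annotation or sequence of mm9 were not run: the share of peaks at promoters, the shares in exons, introns and intergenic sequence, the scores of promoter peaks, the enrichment of fixed gene lists, and motif enrichment. No gene is named as bound. Regions were named by a rule fixed before the data were examined: the 20 peaks with the highest scores, the 5 widest peaks, the 10 windows of 1 Mb with the most peaks, and the count of each chromosome. The largest groups of neighbouring peaks, the strongest peaks of X and the part of chromosome 8 beyond 120 Mb fall outside this rule and were chosen after their values were seen.

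Chromosome lengths of mm9 were not at hand, so the span from the first to the last listed peak stood in for them. Peaks on the 19 autosomes and X were compared with the number expected from the spans by a Monte Carlo goodness-of-fit test with 100000 draws. Each chromosome was tested with an exact two-sided binomial test, Benjamini-Hochberg adjusted over 20 chromosomes. This test treats peaks as independent, which neighbouring peaks are not. A permutation of 5 Mb windows between chromosomes (100000 resamples), which keeps neighbouring peaks together, was added after the chromosome counts had been seen. It takes windows as exchangeable, while density also changed over longer stretches of some chromosomes, so its p-values may be too small. Clustering was measured as the share of peaks whose nearest neighbour lay within 10 kb, edge to edge, against 1000 random placements of the peaks on their own chromosomes. A 1 Mb window was called dense when its count exceeded the 95th percentile of the highest window count in those placements. Median scores were compared by two-sided permutation tests and the relation of score to width by Pearson's r and Spearman's rho, each with 100000 resamples. The smallest p these tests can give is 1e-05, and the smallest from placements is 0.001.

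The alternatives tried were score thresholds of 100 and of the list's median, merging of peaks within 1 kb, other neighbour distances and window sizes, placement within each peak's own 1 Mb window, and other spans. The methods were tested on simulated lists of 5941 peaks. Of 20 lists with random positions, 1 was called clustered, and 1 window was called dense over all 20. A chromosome with a 1.5-fold raised rate was recovered in 20 of 20 lists of independent peaks. Listed peaks lie close together, so this does not show how the binomial test performs on them. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.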

Results

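Genomic sites of Nacc1, a transcription factor with a BTB/POZ domain, were mapped in N2A mouse neuroblastoma cells to ask where a transcription factor linked to the control of splicing sits on the genome. The data comprised 1 ChIP library with a list of peaks and 1 input library without antibody. The comparisons the list allows are between peaks, between regions and between chromosomes.

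The list held 5942 peaks on 21 chromosomes, which covered 2.86 Mb of mm9. The median score was 81.6, with quartiles of 59.2 and 139, where the score is −10 times the log10 of the p-value assigned by the peak caller. A score of at least 100 was reached by 2283 peaks (38.4%), of at least 200 by 933 (15.7%), of at least 500 by 265 (4.46%) and of at least 1000 by 71 (1.19%). The median width was 423.5 bp, with quartiles of 345 and 546 bp and a range from 163 to 9350 bp. Most listed sites were thus narrow and of low score, and a small group of sites stood far above them.

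The 20 strongest sites had scores from 2008 to 3212 and lay on 11 chromosomes. Chromosome 8 carried 4 of them, chromosome 5 carried 3, and X carried 0. The highest listed score, 3212, belonged to a 990 bp peak at chromosome 5, 120744082 to 120745071. A score of exactly 3100 was listed for 5 peaks, at chromosome 9, 45484527 to 45486216, chromosome 10, 41477464 to 41478983, chromosome 5, 33015006 to 33016356, chromosome 6, 142698704 to 142699876, and chromosome 15, 98437760 to 98438545. A second strong site on chromosome 15, at 101975725 to 101976944, had a score of 3097. The sources used here do not explain the shared value of 3100, so no order of strength is read from these scores. The strongest sites of chromosome 8 were at 48448409 to 48449584 (score 2748), 122749426 to 122750539 (score 2359), 129060796 to 129062976 (score 2302) and 28183440 to 28185171 (score 2077). The remaining 9 sites of this group had scores between 2008 and 2902. The group had a median width of 1175 bp and ranged from 748 to 2181 bp. Within it, 9 sites had another listed peak within 10 kb. Some of these gaps were very short, down to 0.006 kb, so such neighbours may not be separate sites. The genes, exons and promoters at these positions were not analysed here.

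Wider peaks had higher scores up to a width of 2000 bp. The median score was 55.6 for the 689 peaks of at most 300 bp, 149.95 for the 1423 peaks of 501 to 750 bp, 536 for the 144 peaks of 1001 to 1500 bp and 951 for the 17 peaks of 1501 to 2000 bp. Across peaks, which are not independent replicates, Spearman's rho was 0.73 and Pearson's r was 0.46 (two-sided permutation tests, p = 1e-05 for each, the smallest they can give; adjusted over both coefficients the value stays 1e-05). Without the 2 peaks farthest from the median width, rho was 0.74 and r was 0.53. Scores of the caller rise with the width of a region, so a positive relation was partly given in advance. The p-values therefore say little about Nacc1 itself. As a class, the 12 peaks wider than 2000 bp departed from this trend, with a median score of 141. They were mixed, with quartiles of 67.5 and 673, and those of 2143 to 2794 bp had scores from 562 to 2302. The widest of all, at chromosome 5, 15017988 to 15027337, spanned 9350 bp at a score of 57.2. On either side of it on chromosome 5 were a 5779 bp peak at 14927087 to 14932865 (score 68.5) and a 4284 bp peak at 15050769 to 15055052 (score 73.2). The other members of the 5 widest were at chromosome 17, 39979889 to 39985953 (6065 bp, score 138), and at chromosome X, 166439786 to 166444662 (4877 bp, score 179).

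**Figure D1:**
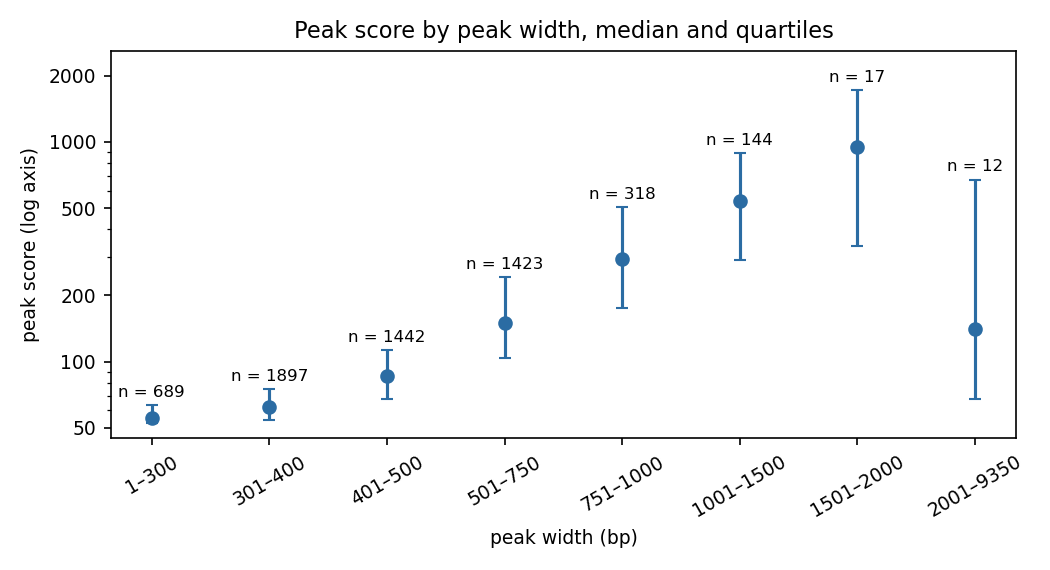
Peak score (log axis) by peak width in bp. Points are medians and bars run from the first to the third quartile over peaks, with the number of peaks above each bar. The median rises from 55.6 in the narrowest class to 951 at 1501 to 2000 bp and is 141 for the 12 peaks wider than 2000 bp.

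Nacc1 peaks were spread unevenly over the chromosomes. Chromosome 8 carried 578 peaks, 1.91 times the 303 expected from its span (95% exact interval 1.76 to 2.06), and chromosome X carried 62, or 0.16 times the 385 expected (0.12 to 0.21). This amounted to 4.50 peaks per Mb on chromosome 8, 0.38 on X and 2.49 over all autosomes. Both differences also passed the permutation of 5 Mb windows between chromosomes, which was added after the counts had been seen. Chromosome 8 had a mean of 22.0 peaks per window and X had 1.78, against 11.4 over all 487 windows (permutation test, adjusted p = 0.0026 and 0.0012).

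In the exact binomial test, 8 chromosomes had more peaks than their spans predicted and 7 had fewer at an adjusted p under 0.05. After chromosome 8, the highest ratios to expectation were 1.42 on chromosome 10 (417 peaks), 1.405 on chromosome 11 (391), 1.35 on chromosome 2 (568), 1.28 on chromosome 19 (173), 1.21 on chromosome 15 (283), 1.14 on chromosome 5 (388) and 1.14 on chromosome 9 (297). The span leaves out any stretch before the first listed peak, which raises a ratio where that stretch is long. The first 1 Mb window wholly inside the span began at 14 Mb on chromosome 9 and 8 Mb on chromosome 5, against 4 Mb on chromosome 8. The ratios of chromosomes 5 and 9 had lower interval ends of 1.03 and 1.02, so this could matter for them. Fewer peaks than expected were listed on chromosome 14, with a ratio of 0.55 (150 peaks), on chromosomes 16 (0.70, 156 peaks), 3 (0.73, 266), 1 (0.79, 356), 18 (0.82, 151) and 4 (0.87, 310), and on X. Chromosomes 6 (333 peaks), 7 (345), 12 (255), 13 (282) and 17 (180) did not pass the test. Over all 20 chromosomes the counts departed from the spans with a Monte Carlo p of 1e-05, the smallest it can give. When 5 Mb windows were permuted, only chromosome 8 and X passed, so the remaining chromosomes did not stand apart from the spread between regions. The Y chromosome had 1 peak and was not tested.

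**Figure D2:**
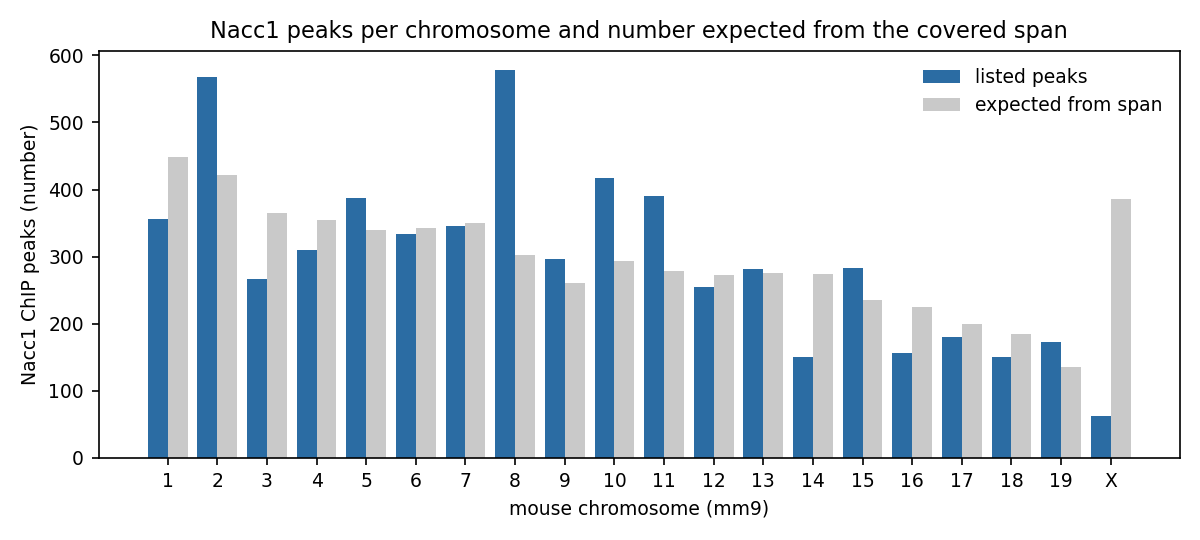
Number of listed Nacc1 peaks per mouse chromosome (blue) beside the number expected from the chromosome's span between its first and last peak (grey). Chromosome 8 stands at 578 against 303 expected and chromosome X at 62 against 385.

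Scores differed less between chromosomes than numbers of peaks did. The median score of the autosomes ranged from 72.3 on chromosome 1 to 90.3 on chromosome 18. Chromosome 8 had a median of 88.7, with quartiles of 59.2 and 144, and X had a median of 65.6, with quartiles of 53.4 and 129. The strongest peaks of X were at 100811359 to 100812044 (score 620) and 104652053 to 104653186 (score 591).

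Many sites lay close together. A neighbouring peak within 10 kb was found for 1694 peaks, or 28.5% (95% Clopper-Pearson interval 27.4% to 29.7%), against a mean of 5.46% and at most 6.65% in 1000 random placements on the same chromosomes (one-sided empirical p = 0.001, the smallest they can give). The excess was also present at shorter and longer distances, with 9.09% of peaks against 0.80% at 1 kb and 55.1% against 23.5% at 50 kb. When each peak was placed at random within its own 1 Mb window, which keeps the regional density, the mean share at 10 kb was 12.3% and the observed share stayed above all 1000 placements (empirical permutation p = 0.001). The 1694 peaks formed 722 groups, of which 561 were pairs and 51 held 4 or more peaks. The largest groups held 10 peaks each, at chromosome 8, 122789519 to 122830354, with a highest score of 630, and at chromosome 13, 23636375 to 23677753, with a highest score of 160. Groups of 7 peaks lay at chromosome 8, 122962673 to 123007305, and at chromosome 2, 173589111 to 173621841.

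**Figure D3:**
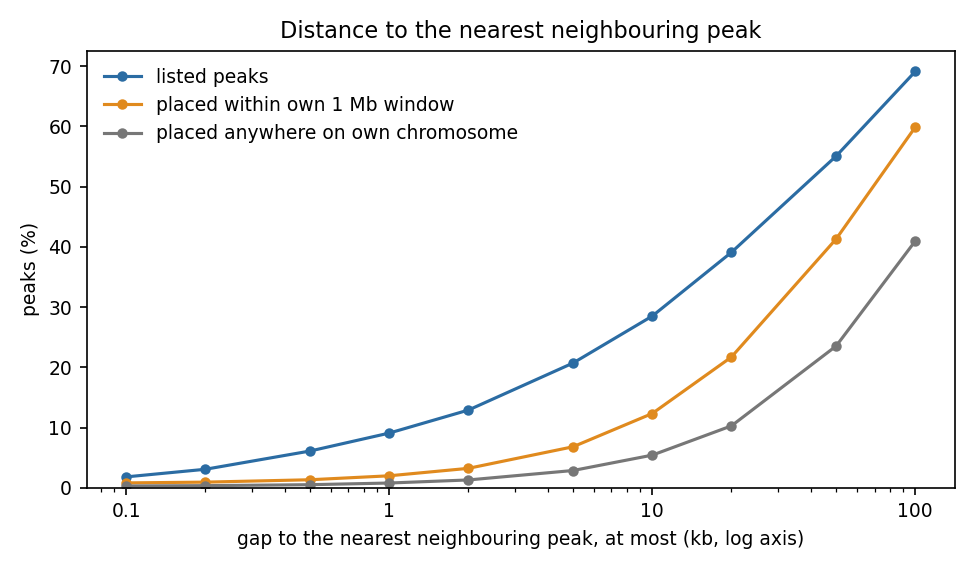
Percent of peaks whose nearest neighbour lies within a given gap (kb, log axis), for the listed peaks (blue) and for the means of 100 placements of the same peaks within their own 1 Mb window (orange) or anywhere on their own chromosome (grey). At 10 kb the listed peaks stand at 28.5%, and the placements at 12.3% and 5.43%. Placed peaks may overlap and then count as neighbours, which listed peaks never do.

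Peaks with a neighbour within 10 kb had higher scores than isolated peaks. Their median score was 95.8 against 76.6 for the other 4248 peaks, a difference of 19.3 (two-sided permutation test, p = 1e-05). The permutation tests of scores shuffled single peaks. Peaks of a group are not independent, so these p-values may be too small. When only the 2283 peaks with a score of at least 100 were kept and neighbours were counted among these, the medians were 178 for 450 peaks with a neighbour and 168 for 1833 without (permutation test, p = 0.12). With the peaks at or above the median score they were 147 for 695 and 137 for 2276, a difference of 9.53 (permutation test, p = 0.035). Both cuts select on the score that is compared and redraw the groups, so neither tests the difference in the full list.

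Dense regions accounted for part of the list. Of all 1 Mb windows, 44 held more than 13 peaks, the limit from random placement, and together they contained 834 peaks (14.0%). Chromosome 8 had 10 of these windows, chromosome 2 had 6, and chromosomes 4, 11 and 13 had 4 each. X had no dense window. At 0.38 peaks per Mb this was likely under a limit set over all chromosomes, so it adds little to the low count of X. The window with the most peaks was chromosome 8, 122000001 to 123000000, with 41 peaks, of which 21 had a score of at least 100. On the same chromosome followed the windows 129000001 to 130000000 (36 peaks), 127000001 to 128000000 (30), 123000001 to 124000000 (26) and 10000001 to 11000000 (25). The part of chromosome 8 beyond 120 Mb took up 8.99% of its span and 36.3% of its peaks. The other windows among the 10 fullest were chromosome 2, 4000001 to 5000000 (29 peaks), chromosome 11, 117000001 to 118000000 (23), chromosome 4, 150000001 to 151000000 (21), chromosome 15, 78000001 to 79000000 (21), and chromosome 19, 57000001 to 58000000 (21). The window on chromosome 11 also held a peak with a score of 2053, and the fullest window of chromosome 8 one with a score of 2359.

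**Figure D4:**
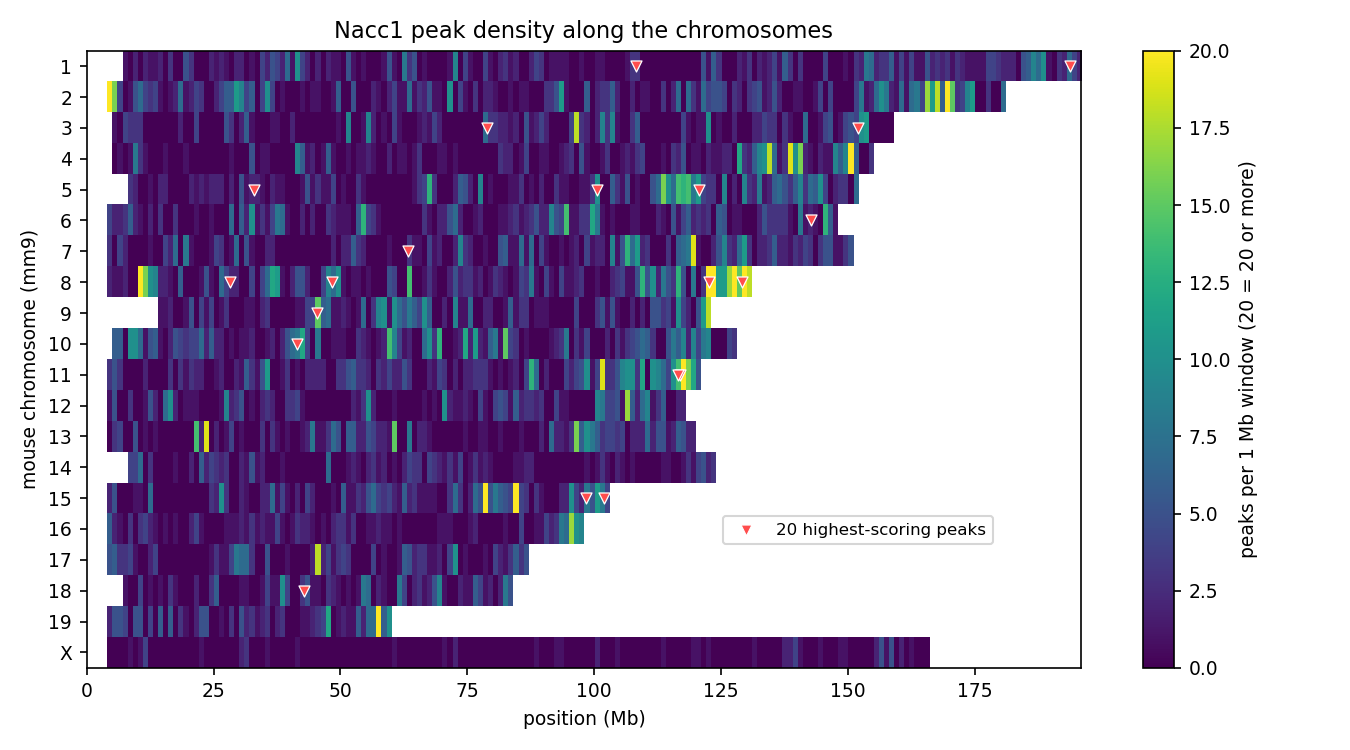
Peaks per 1 Mb window (colour, capped at 20) along the mouse chromosomes of mm9, position in Mb, for windows wholly inside each chromosome's span. Triangles mark the 20 highest-scoring peaks. The distal end of chromosome 8 holds 4 of the 5 fullest windows, and X is nearly empty.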

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

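A score threshold of 100 left 2283 of the 5942 peaks and the median score left 2971, by construction. The number of chromosomes past the binomial test, 15, was 9 at a score of at least 200 and 4 at a score of at least 500, settings added after the data were seen that test fewer peaks, and 2 when 5 Mb windows were permuted, also added, which does not treat neighbouring peaks as independent. The 44 dense windows became 18 at a score of at least 100 and 23 at the median score, with fewer peaks to place, and 17 with 5 Mb windows, which are fewer. The score difference between peaks with and without a neighbour, 19.3, was 9.185 at a score of at least 100 and no longer passed its permutation test (p = 0.12), and at the median score it was 9.53 and passed (permutation p = 0.035); both settings select on the score compared and redraw the groups. In the binomial tests and the window permutation, the ratios of chromosome 8 (1.73 to 2.14) and X (0.12 to 0.18) kept their direction and passed in every setting; the bootstrap interval for chromosome 8 included 1 without its 10 most crowded windows (ratio 1.20) and at a score of at least 500 (1.95). The relation of score to width (rho 0.56 to 0.74) and the excess of neighbouring peaks passed in every setting run. Promoter shares, genomic features, promoter scores, gene lists and motifs were not run, under any alternative, for want of mm9 annotation. With 1 ChIP library no replicate could be left out, and read depth was not analysed here, so how many weaker sites the threshold missed is open.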

Other observations

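All tests in this part were chosen after the counts per chromosome had been seen, and they concern 1 list of peaks without a replicate. Mouse chromosomes other than Y are numbered from the end that carries the centromere. Peaks were denser away from it. Beyond the midpoint of the spans lay 3643 of 5941 peaks, or 61.3% (95% interval from resampling chromosomes 57.4% to 65.2%), and 18 of 20 chromosomes had more peaks there than before the midpoint. The shares were highest on chromosomes 4 (78.1%), 15 (73.1%), 5 (71.6%) and 11 (71.4%), and below 50% on chromosomes 9 (45.5%) and 14 (42.7%). A search for a single step in density along each chromosome, over 5 Mb windows, gave an adjusted permutation p under 0.05 on 7 of 20 chromosomes, and in 7 of these 7 the density was higher beyond the step. The adjusted permutation p lay close to the threshold on chromosomes 1, 2 and 12 (0.049995 each) and 8 (0.0465). On chromosome 4 the density rose from 1.04 to 6.03 peaks per Mb at 125 Mb and on chromosome 11 from 2.07 to 9.15 at 100 Mb.

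The denser distal parts were weighed against 3 explanations. For chance differences between chromosome ends, an exact two-sided binomial test over the 20 chromosomes gave p = 0.000402 for the 18 with more peaks beyond the midpoint, which argues against chance; the split was chosen after the pattern was seen, so this p is not an independent confirmation of it. Sparse peaks next to the centromere do not account for the pattern alone, since without the first 20 Mb of each span the distal share was 63.0% (58.3% to 67.0%). A few crowded regions do not either, since without the 44 dense windows it was 58.5% (55.3% to 61.8%). A hypothesis left open is that Nacc1 sites may follow the density of genes or of open chromatin, which was not tested for want of mm9 annotation.

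The high count of chromosome 8 was also seen at scores of at least 100 and 200. Counted over 1 Mb windows, its ratio to the other autosomes was 1.89 (95% bootstrap interval 1.42 to 2.45) for all peaks. Over 5 Mb windows, 25 on chromosome 8, it was 2.14 (1.14 to 3.44) at a score of at least 100 and 2.09 (1.11 to 3.35) at 200. At 500 it was 1.95 (0.83 to 3.57), from 25 peaks. The rule set beforehand asked for an interval above 1 at 500, and this interval includes 1. By that rule alone, weak peaks close to the calling threshold were not excluded as the cause. The exact binomial interval at 500, with peaks taken as independent, was 1.28 to 2.76. At 100 and 200 the bootstrap intervals lay above 1, so the excess was not limited to peaks with scores below 200. These values argue against weak peaks as the whole cause in this list. The bootstrap takes windows as independent, so its intervals may be too narrow. Without the 10 most crowded 1 Mb windows of chromosome 8 alone the ratio was 1.20 (0.94 to 1.47), a fall that leaving out the fullest windows of a single chromosome brings by construction. With the same share of windows, 8%, left out on every autosome it was 1.70 (1.34 to 2.09). An ordinary chromosome with 10 crowded windows added would give about 1.43 there, not the 1 set beforehand as the bound, because the other autosomes lose their own crowded windows. That lies inside the interval. Both ratios leave out the same windows of chromosome 8, so this repeats the comparison of 1.20 with 1 and is no separate test. These ratios cannot decide, and a few crowded windows as the whole cause stay open. A higher copy number of the chromosome in these cells may contribute and stays open, since input coverage was not analysed here. Of its 5 Mb windows, 60% (38.7% to 78.9%) exceeded the median window of the other autosomes, an interval too wide to decide. Its density was not even, and rose from 3.12 to 19.0 peaks per Mb at 120 Mb (step search, adjusted permutation p = 0.0465). The median score of chromosome 8 exceeded that of the other autosomes by 7.25 (88.7 against 81.4, two-sided permutation test with peaks taken as independent, p = 0.016). This is not particular to it, since chromosomes 12 (89.0) and 18 (90.3) had higher medians with peak ratios of 0.93 and 0.82.

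The low count of X was not limited to weak peaks: at a score of at least 200 its ratio to the autosomes was 0.16 (95% bootstrap interval 0 to 0.45), against 0.15 (0.08 to 0.24) for all peaks. If the cells had 1 copy of X against 2 of each autosome, and if scores were proportional to copies, X at the listed threshold would match the autosomes at a score of 100. The measured ratio was 0.38 (0.20 to 0.62), lower than this. Neither assumption was tested, so copy number cannot be told apart from fewer Nacc1 sites on X, and both may act. Along X, 31 peaks lay in the last 31.5 Mb (0.98 per Mb) and 31 in the preceding 132 Mb (0.24 per Mb), with 13 and 5 scores of at least 100 (two-sided Fisher's exact p = 0.049). The step itself, at 135 Mb, had an adjusted permutation p of 0.14.

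Of the peaks wider than 2000 bp, 5 had scores below the list's median. Of these, 3 lay within 1 Mb of another such peak or of an end of the covered span, as did 155 of the other 5937 peaks (2.61%, one-sided Fisher's exact p = 0.000177). All 3 belonged to the single stretch of chromosome 5 between 14927087 and 15055052, so they are not independent. The comparison was set up to weigh repeated or collapsed sequence in the assembly as the source of wide low-score peaks. Resting on 1 stretch, it cannot decide. Whether the wide low-score peaks are sites of Nacc1 stays open. Separately, 108 peaks (1.82%) had a neighbour within 0.1 kb, against 0.31% in random placements on the chromosome and 0.82% in placements within each peak's own 1 Mb window, and the smallest gap between listed peaks was 1 bp.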
